A study of Homo sapiens with 15 samples.

How the data were processed

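The series holds 15 ChIP-seq samples of K-562 cells, of which 2 had a processed file used here: MPP8 in TASOR KO cells and MPP8 in TASOR2 KO cells, 1 library each. Per the labels' protocols, knockout clones were made with CRISPR/Cas9, cells were fixed with 1% formaldehyde for 10 min, chromatin was cut with micrococcal nuclease and sonication, 80 µg of human chromatin received mouse chromatin at 1 part in 40 as a spike-in, and libraries were amplified with 13 cycles. Samples were grouped by their titles. The input, unedited, PPHLN1, MPP8 and double knockout, transgene, TASOR and TASOR2 samples were not used here.

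Per the submitters' processing notes, Bowtie2 2.3.5.1, MACS2 and deepTools were used with the builds hg38 and mm9. The control library, thresholds and use of the spike-in in peak calling are not given in the sources used here. The deposited peak lists have no header and 9 columns in the order that MACS2 writes for broad peaks. Peaks were called by the authors per sample, as each list names a single library. The deposited score equalled the whole part of 10 times the deposited −log10 q in all 427 TASOR KO and all 264 TASOR2 KO peaks. The deposited fold enrichment (a ratio) and the −log10 p and −log10 q are the authors' own values per peak, read from the column order. Peak names in the lists carry a tag of 0.5 in TASOR KO and 0.3 in TASOR2 KO, and peak numbers with gaps that run from 1612 to 13397 and from 1 to 1512. The lists are therefore parts of longer numbered lists, and how the parts were chosen and what the tags mean are not given in the sources used here. The largest q was 0.460 in TASOR KO and 0.258 in TASOR2 KO, each below the number in its tag. A looser q threshold in TASOR KO would give this, but none is stated. The lists could thus differ through thresholds or selection as well as through genotype. The smallest −log10 q was 0.337 in TASOR KO and 0.588 in TASOR2 KO, and many peaks are weak by that measure. Total reads per library are not given in the lists, so the depth is unknown.

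Coordinates are printed 1-based on hg38. Gene positions came from a RefSeq gene table of the same assembly (59665 genes on the assembled chromosomes, 20037 of them protein-coding). It has neither strand nor exons, so the planned share of peaks at transcription starts was replaced by the share within 1 kb of either gene end, and exon and intron shares were not computed. No genome sequence was used, so the planned shares of peaks with LINE-1 sequence, positions along LINE-1 and the 10 planned motifs were not analysed here.

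Overlap meant 1 bp or more. Shares carry exact (Clopper-Pearson) binomial 95% intervals. The lists were compared by the conditional odds ratio with its exact 95% interval, which compares the 2 lists and not the genotypes. Shares were set beside 1000 random placements of each peak on its own chromosome at its own width, between the first and last annotated gene base, since chromosome lengths were not used here. Medians of width carry order-statistic 95% intervals. For 9 gene lists fixed before the data were examined, the number of genes with a peak in the body or within 1 kb of an end was set beside 10000 random lists of protein-coding genes matched on length in 20 bins. This matching ignores that genes of a family lie in clusters. No p-value was computed. The genes named in the text followed a rule fixed before the data were examined: the 12 peaks of highest score per list with the gene they lie in, up to 8 genes of each gene list with a peak at an end or, where none, up to 4 with a peak in the body, up to 10 shared peaks, and the loci of TASOR, TASOR2, MPHOSPH8 and PPHLN1. Genes outside the rule are said to be chosen after their values were seen.

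The gene list step was tested on simulated data before use. In 200 simulations with peaks placed at random, the list of 108 interferon-stimulated genes exceeded the random range in 1.0% for the TASOR KO and 0.0% for the TASOR2 KO list, and with peaks planted at 15 of its genes it did so in 100.0% for both. Alternatives fixed before the data were examined were the higher-scoring part of each list, a reciprocal overlap of 50%, peaks extended by 1 kb, leaving out chromosomes 9 and 22 or chromosome 19, a window of 5 kb, and the ends of all annotated genes. Alternatives added after seeing the data were a common q threshold, an equal number of peaks, and leaving out chromosome 1 or 7, and for the ZNF share of peaks also chromosome 19. The random shifts of up to 20 kb were also added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.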

Results

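MPP8 binding was measured by ChIP-seq in K-562 cells, a line established from a chronic myeloid leukaemia. MPP8 is a chromodomain protein that recognises methylated histone H3 lysine 9 and acts in the human silencing hub (HUSH), a complex that represses LINE-1 elements and other invading DNA. TASOR is the scaffold of that complex and TASOR2 is its paralog. Peak lists of 2 samples were analysed, 1 library from cells without TASOR (TASOR KO) and 1 from cells without TASOR2 (TASOR2 KO), both precipitated with an antibody to MPP8. The other 13 samples of the series, among them input chromatin and MPP8 ChIP in unedited and in MPP8 knockout cells, were not used here, so how much of the signal in a peak was not due to MPP8 was not measured. With 1 library per genotype there was no replicate error, so no p-value was computed, and each interval covers counting error only and treats peaks as independent. The differences given are differences between these 2 lists.

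The first question was where MPP8 was detected when each paralog was absent. The TASOR KO list held 427 peaks on 21 chromosomes with a median width of 1929 bp (95% order-statistic interval 1769 to 2044), and the TASOR2 KO list held 264 peaks on 19 chromosomes with a median width of 1881.5 bp (1690 to 2041). They covered 1128 kb and 683 kb. Enrichment was modest in both: the fold values that the authors' peak caller gave ranged from 2.49 to 6.57 (median 3.35) in TASOR KO and from 2.61 to 6.01 (median 3.92) in TASOR2 KO, and these folds were used only to describe peaks. Peaks were ranked within a list by the authors' −log10 q, and the strongest peaks are those of highest −log10 q, not of highest fold. A q of 0.05 or less was reached by 138 peaks (32.3%) in TASOR KO and by 79 (29.9%) in TASOR2 KO, and the largest q was 0.460 and 0.258. Sequencing depth is not given in the peak lists, so the depth behind each peak is unknown.

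The strongest TASOR KO peak lay on chromosome 8 at 128375192 to 128386207 (hg38, fold 5.79), outside any annotated gene and 632241 bp from the nearest protein-coding gene end, that of MYC. It was followed by peaks at the zinc finger gene ZNF200 (chromosome 16, 3230530 to 3240497, fold 5.63), at THADA (chromosome 2, 43593273 to 43597427, fold 6.50), at FAM111A, which encodes a protease that restricts viral replication (chromosome 11, 59141985 to 59145227, fold 6.40), and at HERC6, an interferon-stimulated gene (chromosome 4, 88378793 to 88379616, fold 6.57). The other 7 of the 12 strongest lay in the noncoding genes LOC101928721, LOC124901175 and LINC00944, across ZNF534 and ZNF578 (17390 bp, the widest peak of the list), in the interferon-stimulated gene DDX60, 4894 bp from an end of ATP23, and across MMUT and CENPQ.

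The strongest TASOR2 KO peak lay inside another zinc finger gene, ZNF175 (chromosome 19, 51587413 to 51588664, fold 6.01). Peaks inside MYO1F, which encodes a myosin (chromosome 19, 8552868 to 8555814, fold 5.69), and inside ANKRD11, a chromatin regulator gene (chromosome 16, 89280121 to 89285183, fold 5.27), were among the next. The other 9 of the 12 strongest lay in ITGB1BP1, TMEM70, CPED1, the amino acid transporter gene SLC38A1, ZNF12, ZNF888, MKI67, which encodes the proliferation marker Ki-67, and, with 2 peaks, the noncoding gene LINC01667 on chromosome 21.

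Both lists were concentrated on chromosome 19, which carries 246 of the 509 ZNF genes and held 60 TASOR KO peaks (14.1%) and 65 TASOR2 KO peaks (24.6%) in 1.90% of the annotated span of the genome. Chromosome 7, with 5.16% of that span, held 90 (21.1%) and 44 (16.7%). No TASOR KO peak lay on chromosome 1, where the TASOR2 KO list had 19. Peak numbers in the TASOR KO list began at 1612, on chromosome 10, and ran to 13397, so that this list is part of a longer numbered series of calls, and the absence of chromosome 1 cannot be read as an absence of binding.

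The second question was whether MPP8 occupied the same places without TASOR as without TASOR2. No peak was shared: 0 of 427 TASOR KO peaks (exact binomial 95% upper bound 0.860%) and 0 of 264 TASOR2 KO peaks (upper bound 1.39%) overlapped a peak of the other list by 1 bp or more. Both lists are parts of longer numbered lists, and a removal of overlapping peaks before deposit stays open. These bounds therefore describe the deposited peaks, not MPP8 occupancy. Peaks placed at random on their own chromosomes gave a mean of 0.605 overlapping TASOR KO peaks, and 54.4% of the 1000 placements also gave none, so the lack of overlap was not unusual against chromosome-wide placement. That placement ignores that the peaks lay near each other. When TASOR KO peaks were instead shifted at random by up to 20 kb, a mean of 3.38 overlapped a TASOR2 KO peak and 2.7% of 1000 draws had no overlap. Within 100 kb of a TASOR KO peak lay 74 TASOR2 KO peaks (28.0%), against 5.51% on average after random placement and 8.33% at the upper end of the central 95% of placements. In the other direction the count was also 74 (17.3%, against 3.42% on average). Within 10 kb the counts were 16 TASOR KO peaks (3.75%, against 0.601%) and 13 TASOR2 KO peaks (4.92%, against 1.00%). None of the 1000 placements reached the observed counts at either distance. Within 1 kb lay 2 TASOR KO and 2 TASOR2 KO peaks, counts that 21.3% and 18.9% of placements reached, so proximity at that distance was not unusual.

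Zinc finger genes made up most of the genes with peaks of both lists. A peak of each list lay in the body of 31 protein-coding genes, where independent lists matched on gene length would share 2.45. Of these 31 genes, 25 were ZNF genes, against 10.0 expected from the 59 and 76 ZNF genes with a peak in either list. ZNF721, ZNF266 and ZNF227 were examples, chosen after their values were seen. In ZNF721 and ZNF266 the peaks of both lists had a q of 0.05 or less. Among the other shared ZNF genes, this held only for ZNF268 and ZNF850. In ZNF227 the TASOR2 KO peak was weak (rank 195 of 264, −log10 q 0.799). The shared genes were counted without a q threshold, and most of the 25 thus rest on a peak with a q above 0.05. Sharing among peaks with a q of 0.05 or less was not tested against an expected count. In ZNF266 (gene ID 10781, chromosome 19, 9412429 to 9435573) the TASOR KO peak covered the upper end of the gene (9434754 to 9437433) and the TASOR2 KO peak its lower end (9410637 to 9413141). The other 6 shared genes were XRN1, CD2AP, CENPQ, STXBP5, CNTNAP2 and ZSCAN32, against 1.25 expected. A TASOR KO peak in ZSCAN32 (rank 88) also lay in ZNF174, which is among the 25, so the 6 are not fully independent of the 25. Whether the 2 lists were called against the same control library is not given in the sources used here, and a shared control could add to such sharing.

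**Figure D1:**
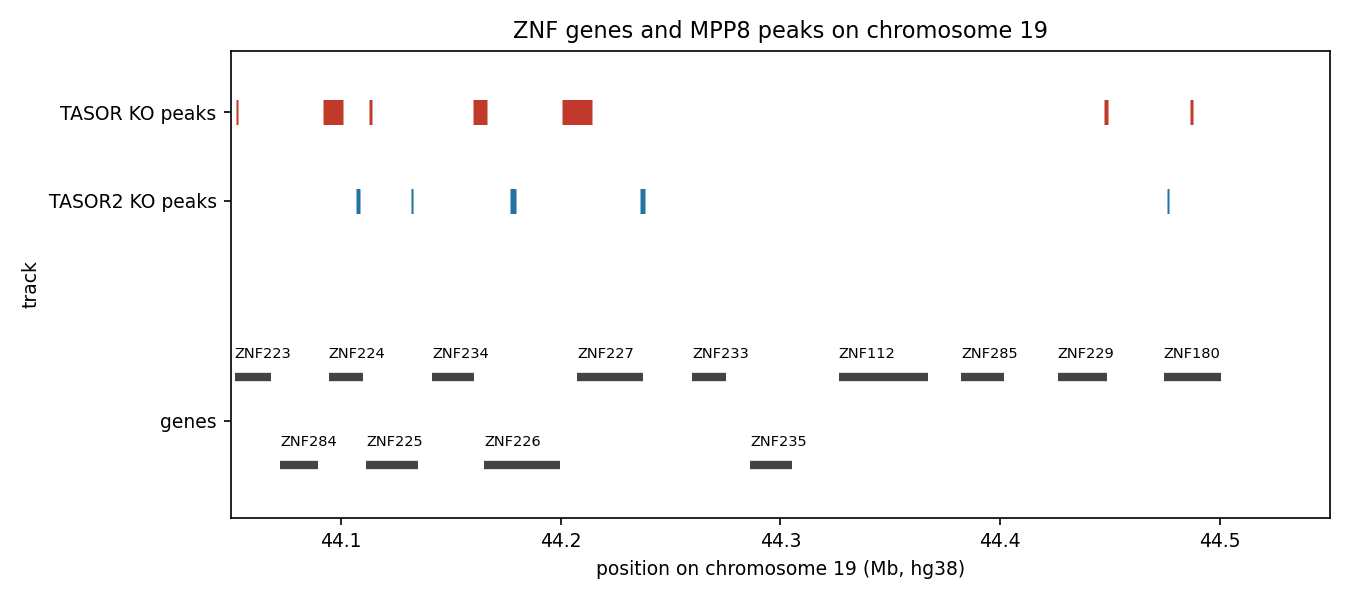
Map of the 0.5 Mb window with the most ZNF genes carrying a peak of each list, chromosome 19 from 44.05 to 44.55 Mb (x axis, position in Mb, hg38), with TASOR KO peaks (red), TASOR2 KO peaks (blue) and ZNF genes (grey) on separate tracks drawn to scale. The 7 TASOR KO and 5 TASOR2 KO peaks are interspersed along the cluster without overlap, and 5 genes carry a peak of each list.

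The third question was which gene features MPP8 occupied. TASOR KO peaks were found more often at the ends of genes and TASOR2 KO peaks more often inside them. Of the TASOR KO peaks, 118 (27.6%, exact binomial 95% interval 23.4 to 32.1) lay within 1 kb of an end of a protein-coding gene, against 39 TASOR2 KO peaks (14.8%, 10.7 to 19.6), an odds ratio of 2.20 (exact 95% interval 1.46 to 3.38). Random placement gave 6.73% and 8.07%. The gene table used here has no strand, so a gene end can be a transcription start or a transcript end. The odds ratio was 3.52 (2.28 to 5.53) at a common q threshold and 3.51 (2.27 to 5.51) with equal numbers of peaks. The order depended on the window: within 5 kb the odds ratio was 0.739 (0.531 to 1.03).

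Protein-coding genes contained 172 TASOR2 KO peaks (65.2%, 59.1 to 70.9, against 47.8% after random placement) and 229 TASOR KO peaks (53.6%, 48.8 to 58.4, against 46.4%). The odds ratio of TASOR2 KO over TASOR KO was 1.62 (1.16 to 2.25). With as many TASOR KO as TASOR2 KO peaks, taken by score, the odds ratio of TASOR KO over TASOR2 KO moved from 0.619 to 0.749 (0.518 to 1.08) and its interval included 1. ZNF genes, counted among the protein-coding genes, held 77 of the 172 TASOR2 KO peaks and 65 of the 229 TASOR KO peaks. The shares without ZNF genes were not compared, so this difference cannot be told apart from that in ZNF genes, given below. No annotated gene of any kind was met by 133 TASOR KO peaks (31.1%) and 51 TASOR2 KO peaks (19.3%).

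**Figure D2:**
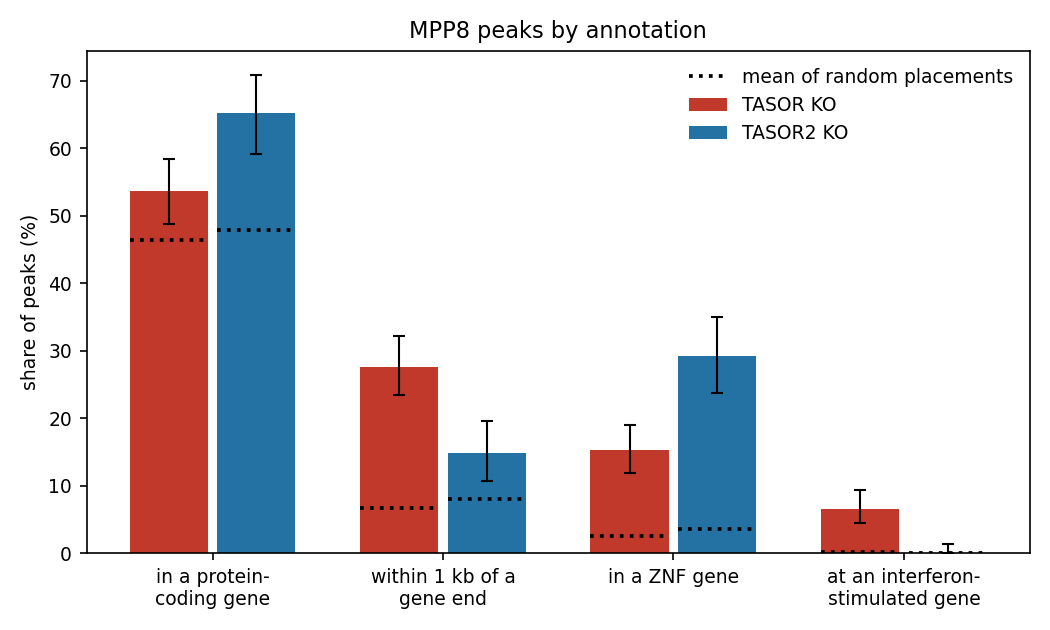
Share of MPP8 peaks (y axis, percent) in protein-coding genes, within 1 kb of a protein-coding gene end, in ZNF genes and at interferon-stimulated genes (the gene or within 1 kb of it), for the TASOR KO (red, 427 peaks) and TASOR2 KO (blue, 264 peaks) lists, with exact binomial 95% intervals and, dotted, the mean of 1000 random placements. Gene ends were met by 27.6% of TASOR KO and 14.8% of TASOR2 KO peaks, and ZNF genes by 15.2% and 29.2%.

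The fourth question was which groups of genes carried MPP8. Interferon-stimulated genes carried peaks in TASOR KO and none in TASOR2 KO. In TASOR KO cells 27 of 108 listed interferon-stimulated genes had a peak in the gene body, where length-matched random gene lists had a median of 1 (central 95% 0 to 3), and 24 had a peak within 1 kb of a gene end. None of the 10000 random lists reached either count. In TASOR2 KO cells 0 of the 108 genes had one (random median 1, 0 to 3). Counted as peaks, 28 of 427 TASOR KO peaks (6.56%, 4.40 to 9.34) and 0 of 264 TASOR2 KO peaks (upper bound 1.39%) lay in or within 1 kb of such a gene, and the exact 95% interval of the odds ratio began at 4.64.

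The 8 interferon-stimulated genes with the strongest TASOR KO peak at a gene end were HERC6, TAP2, which encodes a subunit of the peptide transporter of antigen presentation, NMI, the antiviral gene SAMD9, SP140L, IFIT1, whose product binds viral RNA, TMEM140 and the transcription factor gene IRF2. Their folds ran from 6.57 at HERC6 to 3.82 at TMEM140. At TAP2 (gene ID 6891, chromosome 6, 32821831 to 32838739) the peak spanned the upper end of the gene, 32838180 to 32839647, with a fold of 4.67. At IFIT1 (gene ID 3434, chromosome 10, 89392623 to 89406487) it spanned the lower end, 89390162 to 89393230, with a fold of 4.43. Others, chosen after their values were seen, were the antigen presentation gene B2M (fold 2.91) and MX1, which encodes an antiviral GTPase (fold 2.83). They ranked 404 and 424 of 427. Among the 28 peaks, 21 (75%) were within the 213 highest-scoring TASOR KO peaks. The median rank of the 28 was 138.5, and a q of 0.05 or less was reached down to rank 138. Many of the 28 peaks, some of the 21 among them, thus had a q above 0.05. The 27 genes formed 18 loci when genes closer than 500 kb were joined, on 8 chromosomes, so neighbours such as TAP1 and PSMB9, which share a peak, are not independent.

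**Figure D3:**
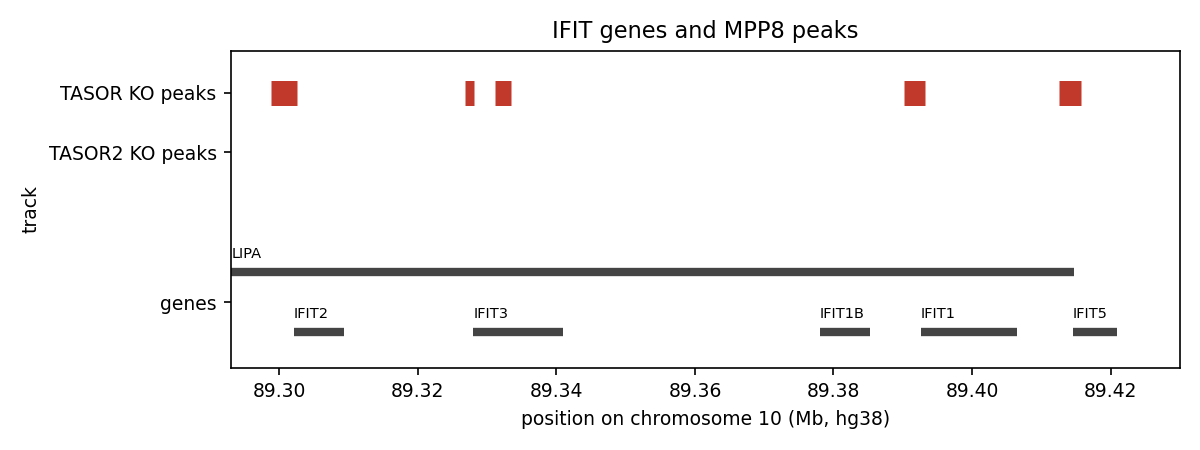
Map of the IFIT genes on chromosome 10 (x axis, position in Mb, hg38) with TASOR KO peaks (red), TASOR2 KO peaks (an empty track) and protein-coding genes (grey, cut at the edges of the window) drawn to scale. The 5 TASOR KO peaks lie at IFIT2, IFIT3 (2 peaks), IFIT1 and IFIT5, and 0 TASOR2 KO peaks lie in the window.

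ZNF genes, most of which encode zinc finger proteins that bind DNA, carried MPP8 peaks in both knockouts. In TASOR KO cells 59 of 509 ZNF genes had a peak in the body (random median 6, central 95% 2 to 11), and in TASOR2 KO cells 76 had one (random median 6, 2 to 11). None of the 10000 random lists reached either count. As a share of peaks, ZNF genes took 29.2% of the TASOR2 KO list (77 peaks, 23.8 to 35.1) and 15.2% of the TASOR KO list (65 peaks, 11.9 to 19), an odds ratio of 2.29 (1.55 to 3.39). Chromosome 19 held 44 of the 59 and 54 of the 76 genes. Without it 15 and 22 ZNF genes remained, still above the central 95% of random lists (0 to 6 and 0 to 5). Most ZNF gene peaks in both lists had a q above 0.05. Their median rank was 173 in TASOR KO and 123 in TASOR2 KO. A q of 0.05 or less was reached down to ranks 138 and 79. With the 213 and 132 highest-scoring peaks, both lists had 40 ZNF genes with a body peak. At the common q threshold the counts were 50 and 76. With equal numbers of peaks they were 49 and 76. The 213 and 132 peaks differ in number, and ZNF genes took 18.3% and 30.3% of them. The equal counts of 40 thus need not mean that the order of 59 and 76 rests on weaker peaks. Counts at a q of 0.05 were not computed.

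Peaks lay closer to the ends of ZNF genes in TASOR KO than in TASOR2 KO at a window of 1 kb. Of the ZNF genes with a TASOR KO peak, 45 of 59 (76.3%, 63.4 to 86.4) had one within 1 kb of a gene end, against 23 of 76 (30.3%, 20.2 to 41.9) of those with a TASOR2 KO peak. Within 5 kb the shares were 50 of 59 (84.7%, 73.0 to 92.8) and 62 of 76 (81.6%, 71.0 to 89.5), with overlapping intervals. Over all 509 ZNF genes the order turned, from 48 and 26 genes with a peak within 1 kb of an end to 59 and 70 within 5 kb. The median distance from the centre of the strongest peak to the nearer gene end was 0.794 kb (quartiles 0.320 and 2.14) in TASOR KO and 2.98 kb (1.56 and 6.54) in TASOR2 KO. The ZNF genes with the strongest TASOR KO peaks at an end were ZNF200, ZNF534, ZNF578, ZNF528, ZNF880, ZNF226, ZNF227 and ZNF229, with folds from 5.80 to 4.66. ZNF534 and ZNF578 shared a peak, as did ZNF528 and ZNF880, and ZNF226 and ZNF227. In TASOR2 KO the genes were ZNF12, ZNF721, ZNF160, ZNF14, ZNF92, ZNF587, ZNF814 and ZNF266, with folds from 4.85 to 4.11. Of these, ZNF587 and ZNF814 shared a peak.

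**Figure D4:**
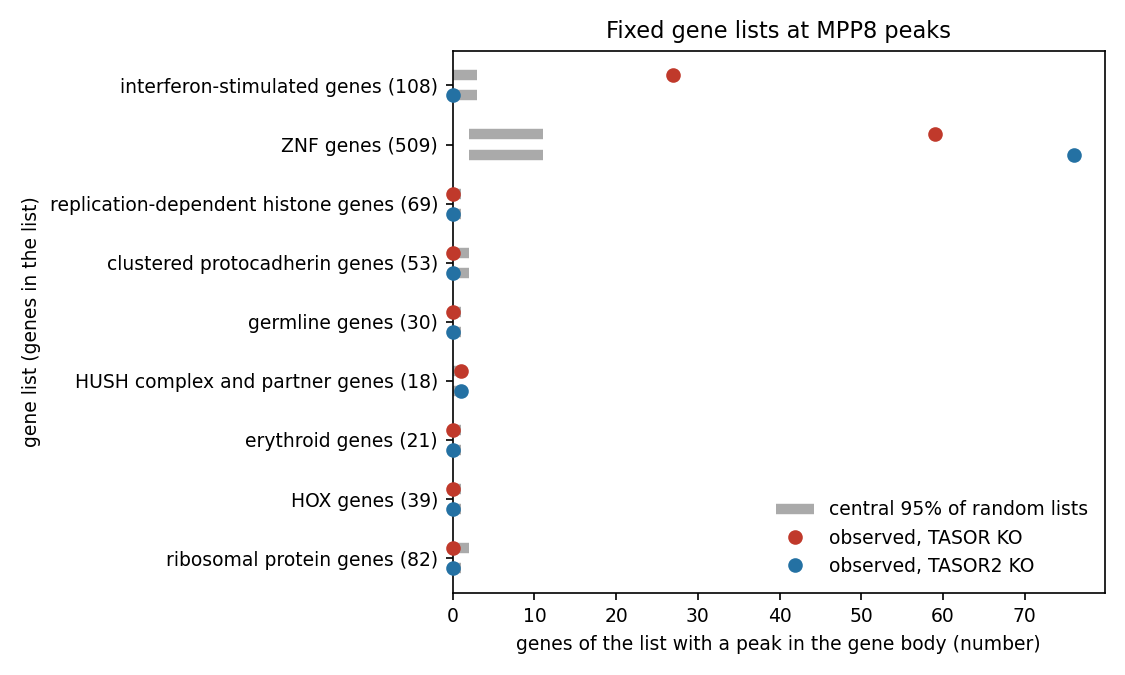
Number of genes with an MPP8 peak in the gene body (x axis) for the 9 gene lists fixed before the data were examined (y axis, list size in parentheses), in TASOR KO (red) and TASOR2 KO (blue), beside the central 95% of 10000 length-matched random lists (grey bars). Interferon-stimulated genes stand at 27 and 0, ZNF genes at 59 and 76, and each other list at 0 or 1.

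The remaining lists were nearly empty. No gene body of the 69 replication-dependent histone genes, 53 clustered protocadherin genes, 30 germline genes, 21 erythroid genes, 39 HOX genes and 82 ribosomal protein genes carried a peak in either knockout. Within 1 kb of a gene end the same lists had 1 peak, at RPS12 in TASOR KO (chromosome 6, 132812742 to 132814223, fold 3.63). Random lists of these sizes mostly held 0 to 2 such genes, so their emptiness was not unusual.

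The genes of the complex itself were examined in each list. In TASOR KO cells a peak spanned the lower-coordinate end of TASOR2 (gene ID 54906, chromosome 10, 5684838 to 5763740), from 5681793 to 5688613, with a fold of 4.95 and rank 16 of 427. It began 3045 bp before the annotated gene. TASOR, MPHOSPH8, which encodes MPP8, and PPHLN1, which encodes the HUSH subunit periphilin, had 0 peaks in either list. MPHOSPH8 lies on chromosome 13, where the TASOR KO list had no peak. Of the 18 genes of the complex and its partners, the other with a peak was ATF7IP2 in TASOR2 KO (chromosome 16, 10469638 to 10471346, inside the gene, fold 4.46). A count of 1 lay within the central 95% of random lists (0 to 1) in both knockouts. Peaks at these loci do not test the knockouts.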

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

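The common threshold, the equal number of peaks, leaving out chromosome 1 or 7 and, for shares of peaks, chromosome 19 were chosen after seeing the data. Of 179 alternative values over 27 results, at least 63 could not move, being subsets of a count of 0 or settings that left that list as it was. Of the other 116, 88 stayed within the interval, the side of 1 or 1.5 times the count of the main value, and 28 did not. Some of the 88 could not move either, as no counted gene lay on the chromosome left out. Examples are interferon-stimulated genes in TASOR KO without chromosome 19 and ZNF genes in TASOR2 KO without chromosome 1. The extension by 1 kb, which among the overlap alternatives could raise the count of 0, gave 0.703% of TASOR KO and 1.14% of TASOR2 KO peaks. All 31 alternative counts outside those 63, of ZNF genes in either list and of interferon-stimulated genes in TASOR KO, lay above the central 95% of random lists. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out. The LINE-1 and motif alternatives were not run. Depth is unknown and limits how far a missing peak can be read.

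With the 213 and 132 highest-scoring peaks, median widths rose to 2464 and 2361.5 bp, shares at gene ends to 42.3% and 19.7%, shares in protein-coding genes to 59.6% and 72.7% and the share of TASOR KO peaks at interferon-stimulated genes to 9.86%. ZNF genes with a TASOR2 KO peak fell to 40 in the body and 17 at an end, as fewer peaks were counted. With the common threshold (266 TASOR KO peaks) and the equal number, TASOR KO median widths were 2215 and 2196.5 bp and gene end shares 38.0% and 37.9%, and the odds ratio of TASOR KO over TASOR2 KO for protein-coding genes was 0.747 (0.517 to 1.08) and 0.749 (0.518 to 1.08). Without chromosome 7 the TASOR KO gene end share was 32.9%. A window of 5 kb, wider by construction, gave gene end shares of 33.5% and 40.5%, 70 ZNF genes with a TASOR2 KO peak near an end, and an odds ratio turned to 0.739 (0.531 to 1.03). The ends of all annotated genes gave 38.2% and 23.9%. Without chromosome 19, which holds 246 of the 509 ZNF genes, ZNF genes took 5.18% of TASOR KO and 11.1% of TASOR2 KO peaks, and the counts were 15 and 22 in the body and 12 and 6 at an end. Beyond the construction of each alternative, the cause was not tested.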

Other observations

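Each test below was chosen after the result was seen, except that on genes with very long exons. Beyond the fixed list, further genes linked to interferon or antigen presentation carried TASOR KO peaks, noted after their values were seen and not tested as a group. DDX60L, the neighbour of DDX60, had the peak of rank 15 (chromosome 4, 168479315 to 168484445, fold 5.95). Peaks also lay at the apolipoprotein L genes APOL2 (rank 39, fold 4.60), APOL1 (rank 79, fold 4.24) and APOL3 (rank 146, fold 3.82), at the butyrophilin genes BTN3A2 (fold 3.43), BTN2A1 (fold 3.42) and BTN3A3 (fold 3.03), and at ERAP1 and ERAP2, which encode peptidases that trim antigenic peptides (fold 3.89 at a peak across both).

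Among the 40 strongest TASOR2 KO peaks were some, picked after their values were seen, inside SPEN (chromosome 1, 15929002 to 15935524, rank 25), SRRM2 (rank 29), the ZNF list member ZNF292 (rank 30), ASPM (rank 15) and RLF (rank 14), all known for a very long exon. This led to the hypothesis that MPP8 without TASOR2 lies at genes with very long exons. A list of such genes was written from general knowledge after the 40 strongest peaks of each list had been seen and without their genes, and 64 were in the gene table. A TASOR2 KO peak lay in 5 of the 64 (CENPF, BOD1L1, MAP1B, RESF1 and AKAP11), where 0.13% of 10000 length-matched random lists had as many (median 1, central 95% 0 to 3). A TASOR KO peak lay in 1, TRANK1 (median 1, 0 to 4). The counts are consistent with the hypothesis for TASOR2 KO. Exon positions were not used here, so whether the peaks lie in the long exons was not tested, and neither was the difference between the lists.

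TASOR KO peaks stood at 25% of the interferon-stimulated genes (27 of 108, exact 95% interval 17.2 to 34.3). A technical explanation is that ChIP signal collects at strongly transcribed genes of any kind. That would put peaks at ribosomal protein, histone and erythroid genes too, but 1 of 172 such genes (0.581%, 0.0147 to 3.20) had one. That count argues against it only if the deposited peaks were not selected against another library. Such a selection could have removed peaks at these genes, whose strong transcription was assumed. Signal that follows transcription raised in the knockout itself stays open, as does a selection of the deposited peaks against another library, since expression and the other libraries were not used here. The TASOR genotype itself also stays open and was not tested, as that needs MPP8 ChIP in unedited and MPP8 knockout cells.

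Chromosome 7 held 21.1% of the TASOR KO peaks in 5.16% of the annotated span. ZNF clusters do not account for it, as 3.33% of these 90 peaks (0.693 to 9.43) lay in a ZNF gene. A gained or high-background chromosome, which gives weak calls, may contribute: chromosome 7 took 29.4% of the 214 lower-scoring and 12.7% of the 213 higher-scoring peaks, an odds ratio of 2.87 (1.70 to 4.93). The higher-scoring peaks still exceeded the span (8.52 to 17.9%), and in TASOR2 KO the odds ratio was 1.11 (0.554 to 2.25), so weak calls need not be the whole cause. No other biological explanation was tested.

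The lists had no overlap although 31 genes carried peaks of both. Unrelated places are argued against as the cause, since 28.0% of TASOR2 KO peaks lay within 100 kb of a TASOR KO peak, against 5.51% after random placement (central 95% to 8.33%). After random shifts of TASOR KO peaks by up to 20 kb, a mean of 3.38 met a TASOR2 KO peak (central 95% 0 to 7), and 2.7% of 1000 draws had none, so chance among neighbouring peaks stays open. So does a removal of overlapping peaks before deposit: the flanking peaks of the other list had consecutive numbers, with no call missing between them, for 6 of 209 TASOR2 KO peaks and 78 of 349 TASOR KO peaks, and with 427 peaks kept of numbers up to 13397, gaps occur beside most places. Binding at different positions in the same genes stays open too. Strongest peaks in ZNF genes were centred a median 0.794 kb from the nearer gene end in TASOR KO and 2.98 kb in TASOR2 KO. Chance, removal and different positions cannot be told apart, because the longer numbered lists were not used here.

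For the 25 ZNF genes with a peak of each list, the hypothesis that the peaks lie at opposite ends of the gene was tested by the side of the gene's midpoint on which each list's strongest peak was centred. The sides were opposite in 18 genes (72.0%, 50.6 to 87.9), against a median of 15 (central 95% 11 to 20) for random positions without overlap in the same genes, and 18.9% of random draws had as many. The count was not unusual, so the test left this hypothesis undecided.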
